A study of Selaginella moellendorffii with 8 samples.

How the data were processed

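RNA from shoot, root, rhizophore and leaf of Selaginella moellendorffii was sequenced in 8 libraries, 2 per organ. Per the labels, 40 excised tissues were pooled per sample, libraries were made with the Nugen Ovation Amp V2 DR kit, and 50 bp single-end reads came from an Illumina HiSeq instrument. The labels call the libraries of an organ biological repeats but do not say whether they came from separate plants, so p-values measure the spread between these samples. Plants were propagated from stem cuttings at 80% humidity under 16 h of light and 8 h of dark.

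The authors deposited a table of raw read counts per gene model, with 1 column per library, and a table of normalized counts averaged per organ, both described so per the file headers. The counts were whole numbers and none lay between 1 and 4 in any library, so that a count of 5 was the smallest above 0 and a model listed at 0 may have had up to 4 reads. The second table holds a signal per organ that the authors normalized and averaged over replicates; its method, beyond the title line, is not given in the sources used here. The submitters' processing notes name Bowtie2, a read aligner, and edgeR. Versions, the genome build, the annotation and the counting tool are not given in the sources used here, nor is the handling of reads that match several places.

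The count table held 25004 models, 22285 with numeric names and 2719 with names starting in Smoe, and 74 were at 0 throughout. None of the model names (0 of 25004) matched the reference table of gene names, so no model could be named or placed in the genome. For that reason the 19 gene lists written before the data were examined matched no member, and their set tests were not run. In addition, 393 of 13937 models with a mean count of at least 100 formed 197 pairs whose counts lay within 0.1 log2 of each other in all 8 libraries, so reads of such pairs may be split between copies.

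Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, which kept 23662 models and removed 1342, and the robust quasi-likelihood test on all 8 libraries with a term per organ. All 8 were fitted together because 2 libraries per organ leave few degrees of freedom, so the organs share a spread. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a model was counted at an adjusted p under 0.05. P-values printed for single models are adjusted p-values from this test, except in ranges over all alternatives. Those ranges also hold adjusted p-values from DESeq2's test and limma-voom. Levels are CPM scaled by TMM, with means ± SD over 2 libraries, and standard errors come from the log2 fold change and its F statistic. Distances between libraries used log2 CPM with a prior count of 2. Folds against an organ at 0 were computed against 5 counts per library, the smallest value listed above 0, and are lower bounds that cover counting error only. Intervals of shares of counts also cover counting error only, and reads without molecular identifiers are not independent molecules. Intervals of shares of models treat each model as an independent draw.

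A model belonged to a class of growth centres if each test the class names passed in the stated direction. For classes, the overlap of independent lists and 20 simulations of unchanged groups are given beside the counts. The simulations show chance with no effect and with the same spread in all organs. Named models were chosen by a rule set before the data were examined: past the threshold, both libraries of the higher organ above both of the lower, a mean of at least 50 CPM in the higher organ, and the largest absolute log2 fold change. With no annotation the rule allowed 2 per direction and comparison. The leading model of each class followed the same rule.

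The authors' organ averages were fitted as non-negative combinations of the 8 count columns with numpy 2.4.6 and scipy 1.17.1, and 100 bootstrap draws over models gave the error. The labels for every column and sample were kept as given in the count table.

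No pair of libraries of an organ agreed within sampling noise: chi-square per degree of freedom was 13.4 for shoot, 120 for root, 253 for rhizophore and 4.52 for leaf. This argues only against a library deposited more than once, since libraries prepared from 1 pool of RNA would also differ by more than that. The smallest library, leaf replicate 1, held 2826533 counts and the largest, root replicate 2, held 27891111, and 5 counts correspond to 1.30 CPM for leaf and 0.115 CPM for root, averaged over their libraries. The procedure was tested on simulated counts with 50 models changed at each fold. For rhizophore against root it recovered 34% of models changed 8-fold and 62% of those changed 16-fold, with 4 unchanged models called among 21231. For root against shoot the recoveries were 36% and 76%, and for leaf against shoot 40% and 58%. None of the models changed 2-fold was recovered in these 3 comparisons, and 0, 6 and 2% of those changed 4-fold. The simulated counts gave each model the same spread in all organs, whereas the chi-square values above differed widely between organs. The recoveries and the unchanged models called hold for that setting and may differ for these libraries.

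The alternatives were DESeq2's size factors, DESeq2 1.42.0, limma-voom from limma 3.58.1, no filter, a filter of 10 CPM in 2 libraries, the 4 libraries of a pair alone, all libraries except leaf, the replicate number as a block, a log2 fold change of at least 1, an adjusted p under 0.01, and each library left out in turn. A fit that leaves an organ with 1 library assumes that it varies like the other organs. After the data were seen, a fit with the library labelled rhizophore replicate 2 counted as root and a fit without both root libraries were added.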

Results

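RNA was sequenced from 4 organs of Selaginella moellendorffii, a lycophyte whose stem branch points carry angle meristems, from which leafless axes called rhizophores grow and later bear roots. The organs were the young shoot tip, the root, the rhizophore and the whole microphyll, the small single-veined leaf of lycophytes. Each organ had 2 libraries, labelled as biological repeats, and each library came from 40 pooled pieces of tissue. Roots were 10 to 20 days old and 5 to 10 cm long, with a cap and hairs, whereas rhizophores were 4 to 7 days old, 2.5 to 3.5 cm long and had neither. The ages given were 10 to 20 days for shoot and 10 to 14 days for leaf. Organ and age therefore cannot be told apart in comparisons with the rhizophore. Total counts were 15161907 and 15305641 for shoot, 25937179 and 27891111 for root, 10063538 and 11886486 for rhizophore, and 2826533 and 16058139 for leaf, for replicates 1 and 2 respectively. The table held 25004 gene models, identified by number and without gene names, so the models below are described by their levels in each organ and not by function.

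The deposited tables did not give the same account of the library labelled rhizophore replicate 2. The authors' deposited Root average was matched by the count columns with weights of 25.3% for root replicate 1, 25.2% for root replicate 2 and 49.6% for rhizophore replicate 2, and their Rhizophore average was matched by rhizophore replicate 1 at 99.9%. Their Shoot average took 50.0% from each shoot library, and their Leaf average took 44.6% and 55.1% from leaf replicates 1 and 2. In the count table this column carried the rhizophore label, as did its sample. The comparisons keep that label, call the column the library labelled rhizophore replicate 2 where it matters, and give counts without it beside those with it.

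**Figure D1:**
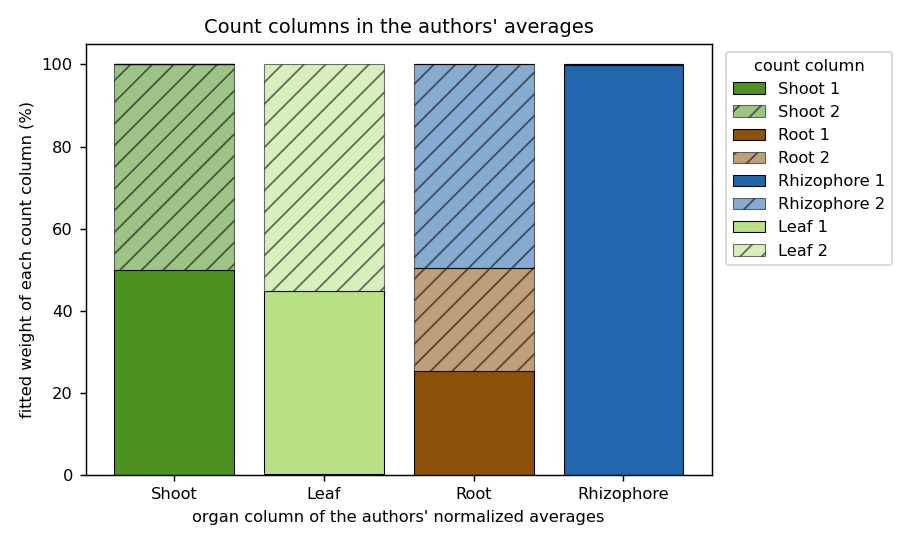
Fitted weight, in percent, of each of the 8 count columns (colours and hatching) in each of the 4 organ averages that the authors deposited (horizontal axis). Shoot and Leaf were made up of their own libraries, whereas the column labelled Rhizophore 2 made up 49.6% of Root and Rhizophore 1 made up 99.9% of Rhizophore.

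Shoot and leaf RNA was dominated by a few models, and root and rhizophore RNA was not. The 10 most abundant models took 33.2% of the counts in each shoot library and 31.8% and 31.6% in the leaf libraries, against 7.95% and 5.44% in root and 9.86% and 4.82% in rhizophore. The most abundant shoot model, 236852.v1, picked after its values were seen, took 10.9% and 10.7% of shoot counts and 10.3% and 10.2% of leaf counts. It took 4.26% and 1.70% of root counts and only 0.0310% and 0.00488% of rhizophore counts. It was lower in rhizophore than in shoot by a log2 fold change of -10.21 (SE 1.35, edgeR adjusted p = 0.000882) and lower than in root by -7.04 (SE 1.19, adjusted p = 0.00338), in both libraries each time, while root against shoot, at -3.17 (SE 0.99, adjusted p = 0.0583), missed the threshold. That last test passed without either rhizophore library (log2 fold change of -2.91 each time). The 95% Wilson intervals of these shares, which cover counting error only, reached at most 0.0543 percentage points to either side. The root libraries listed 24582 and 24858 of the 25004 models above 0, against 17834 and 17914 in shoot, 18720 and 18593 in rhizophore, and 15320 and 19749 in leaf.

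The distances between whole profiles address whether the rhizophore stood nearer to the root or to the shoot. The root mean square difference of mean log2 CPM was 2.49 between rhizophore and root, 2.07 between rhizophore and shoot, and 2.57 between root and shoot. The order of the rhizophore's distances turned with only models at 10 CPM or more in 2 libraries, to 1.95 from root and 2.15 from shoot. Between single libraries, leaf and shoot lay 1.06 to 1.65 apart (mean 1.38), above the 0.97 between the shoot libraries and below the 1.78 between the leaf libraries. The rhizophore libraries lay 1.82 from each other, against 0.97 for the root libraries. Averaged over both rhizophore libraries, the root libraries were 2.69 ± 0.24 away (SD, n = 2) and the shoot libraries 2.29 ± 0.04, and an exact two-sided permutation test gave p = 0.333, the smallest that the 6 assignments of 4 libraries allow. Rhizophore replicate 1 was 2.03 and 1.97 from the shoot libraries and 2.52 and 2.87 from the root libraries. The library labelled rhizophore replicate 2 was about as far from both organs, at 2.61 and 2.56 from shoot and 2.52 and 2.84 from root.

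**Figure D2:**
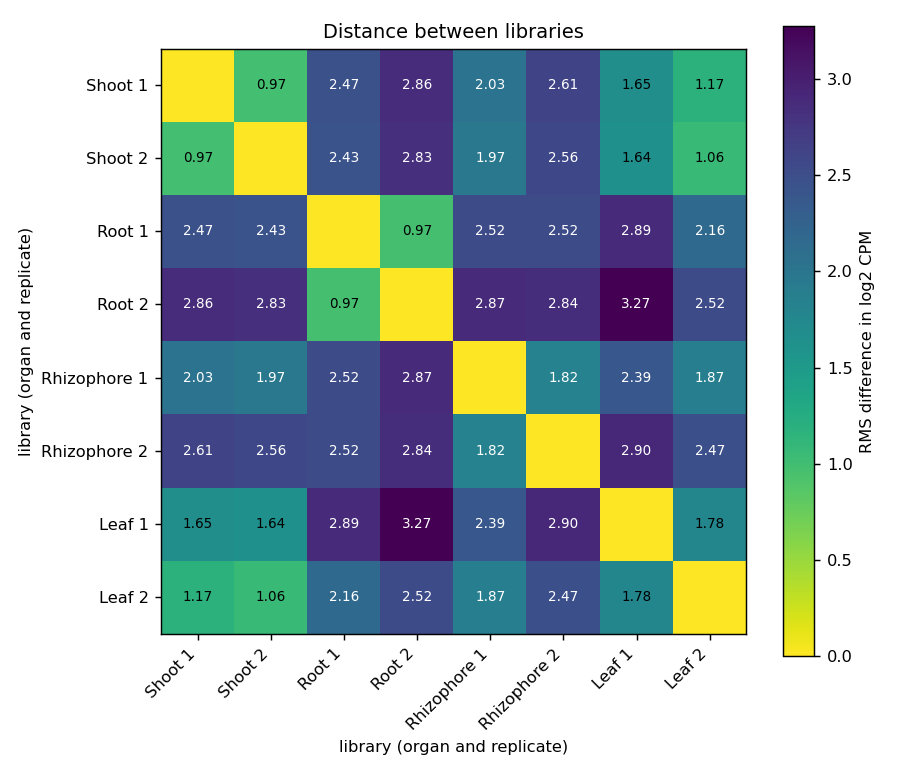
Root mean square difference in log2 CPM between each pair of the 8 libraries, which are named by organ and replicate on both axes; darker cells are farther apart. The rhizophore libraries were 1.82 from each other, whereas the shoot libraries were 0.97 apart and the root libraries 0.97.

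Rhizophores and roots, both outgrowths of the ventral angle meristem per the labels, differed in 8662 of 23662 models tested. Of these, 2803 were higher in rhizophore and 5859 were lower. The model 439279.v1 stood at 5635 ± 1463 CPM in rhizophore (SD, n = 2) and 2.32 ± 0.66 CPM in root, a log2 fold change of 11.24 (SE 0.64, edgeR adjusted p = 4.1e-05). In the authors' deposited table its Root average was 2406, which holds the disputed column. With that column counted as root, which leaves 1 rhizophore library, the fold change was 2.12 and the call ended (edgeR adjusted p = 0.697; 2.0e-236 to 0.697 over all alternatives). The other calls named for rhizophore against root or shoot, except that of Smoe_00049080 against root, ended there too. Where the rhizophore had signal, 91546.v1 fell from 8.06 to 3.23 against root and 440525.v1 from 7.80 to 5.20 against shoot on the log2 scale, whereas for models listed at 0 in both rhizophore libraries the fitted fold change tells nothing about the label. A pair of models was listed at 0 in both rhizophore libraries and was higher in root, but higher still in shoot and leaf. The model 137813.v1 was at 87.4 ± 14.4 CPM in root, 2492 CPM in shoot and 1865 CPM in leaf. It was at least 241-fold higher in root than in rhizophore, against a floor of 5 counts per library (edgeR adjusted p = 6.7e-05). The model 137695.v1 was at 80.0 ± 0.56 CPM in root, 207 CPM in shoot and 146 CPM in leaf. It was at least 220.5-fold higher in root than in rhizophore (edgeR adjusted p = 4.1e-05). The counts of 137695.v1 lay within 0.1 log2 of another model's in all 8 libraries, so its reads may be shared with a copy. The model 89433.v1 was higher in rhizophore by 10.70 on the log2 scale (SE 2.66, edgeR adjusted p = 0.0428), but its level was 374 CPM in rhizophore replicate 1 and 6.02 CPM in the library labelled rhizophore replicate 2, against 0.228 and 0 in root.

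Most of the models lower in rhizophore had low levels in root. Of the 5859, 3890 (66.4%) had a root mean under 10 CPM and 3614 were at 0 in both rhizophore libraries, whereas 66 (2.35%) of the 2803 models higher in rhizophore had a rhizophore mean under 10 CPM. With only models at 10 CPM or more in 2 libraries, 2311 were higher and 2542 lower, and at an adjusted p under 0.01 the split was 1047 higher and 1001 lower. Without the library labelled rhizophore replicate 2 the count was 8902, with 3811 higher and 5091 lower. Counting it as root left 384 models and turned the balance, to 306 higher and 78 lower. The count was 1667 and 1925 without root replicate 1 or 2, 5307 and 5345 without shoot replicate 1 or 2, and 5083 and 5116 without leaf replicate 1 or 2, and the call of 89433.v1 ended in each of these 6 fits (edgeR adjusted p of 0.0546 to 0.111; 2.4e-178 to 0.146 over all alternatives).

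Rhizophores and shoots differed in 5169 models, with 2372 higher in rhizophore and 2797 lower. That balance turned with DESeq2's size factors, at 2708 higher and 2678 lower, with DESeq2's own test, at 4257 and 3580, and without both root libraries, at 2293 and 2231. The leading shoot models were listed at 0 in rhizophore. The model 105500.v1 was at 7067 ± 1098 CPM in shoot (SD, n = 2) and listed at 0 in both rhizophore libraries, at least 19476-fold higher in shoot (edgeR adjusted p = 3.5e-05), and 137813.v1 was at 2492 ± 101 CPM in shoot, at least 6868-fold higher (adjusted p = 1.2e-05). Both leading rhizophore models had most of their signal in the library labelled rhizophore replicate 2. The model 413955.v1 was at 24.6 CPM in rhizophore replicate 1, 277 CPM in replicate 2 and 0 in both shoot libraries (at least 292-fold, edgeR adjusted p = 0.0186), and 440525.v1 was at 36.3 and 404 CPM against 1.97 and 0 CPM in shoot (log2 fold change of 7.80, SE 2.03, edgeR adjusted p = 0.0498). In the authors' deposited table their Root averages, 151 and 220.7, exceeded their Rhizophore averages, 25.6 and 36.3.

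The count for rhizophore against shoot was 7951 without the library labelled rhizophore replicate 2 (4316 higher, 3635 lower), 10366 without replicate 1 (5784 higher, 4582 lower), and 1842 and 1920 without shoot replicate 1 or 2. It was 12 with the library labelled rhizophore replicate 2 counted as root and 1736 in a fit on the 4 libraries of these organs alone (624 higher, 1112 lower), and the calls of 413955.v1 (edgeR adjusted p of 0.0901 and 0.0888; 8.2e-128 to 0.223 over all alternatives) and 440525.v1 (0.104 and 0.171; 9.3e-125 to 0.355) ended without either shoot library, that of 440525.v1 also without leaf replicate 1 or 2 (0.0667 and 0.0649).

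Roots and shoots differed in 3227 models, of which 1239 were higher in root and 1988 lower. The model Smoe_00044417 was at 20918 ± 1315 CPM in shoot (SD, n = 2) and 7.46 ± 1.13 CPM in root, a log2 fold change of 11.45 in favour of shoot (SE 0.98, edgeR adjusted p = 0.000503). The model 442193.v1 was at 7762 ± 1892 CPM in shoot and 10.9 ± 3.77 CPM in root, 9.48 higher in shoot on the log2 scale (SE 0.71, adjusted p = 0.000503). In the other direction, 415652.v1 was at 140.0 ± 72.8 CPM in root and 0 in both shoot libraries, at least 271-fold higher (edgeR adjusted p = 0.0151), and 173016.v1 was at 93.3 ± 72.6 CPM in root and 0 in both shoot libraries, at least 180.5-fold higher (adjusted p = 0.0493).

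The balance of directions between root and shoot depended on the fit. With DESeq2's size factors 49.3% of the differing models were higher in root, against 38.4% in the fit described here, and the median log2 fold change of all models moved by 0.17 from 0.64. DESeq2's own test called 3692 higher and 2818 lower, and limma-voom 6401 higher and 3061 lower. The total was 13526 without the library labelled rhizophore replicate 2 (9661 higher, 3865 lower), 13584 without rhizophore replicate 1 (9800 higher, 3784 lower), 1757 with replicate 2 counted as root, and 13205 with the 4 root and shoot libraries alone (8851 higher, 4354 lower). It fell to 183 and 612 without root replicate 1 or 2 and to 789 and 807 without shoot replicate 1 or 2. The calls of 415652.v1 (edgeR adjusted p of 0.0565 to 0.0745; 1.4e-119 to 0.0745 over all alternatives) and 173016.v1 (0.0717 to 0.202; 2.1e-91 to 0.202) ended in these last 4 fits.

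**Figure D3:**
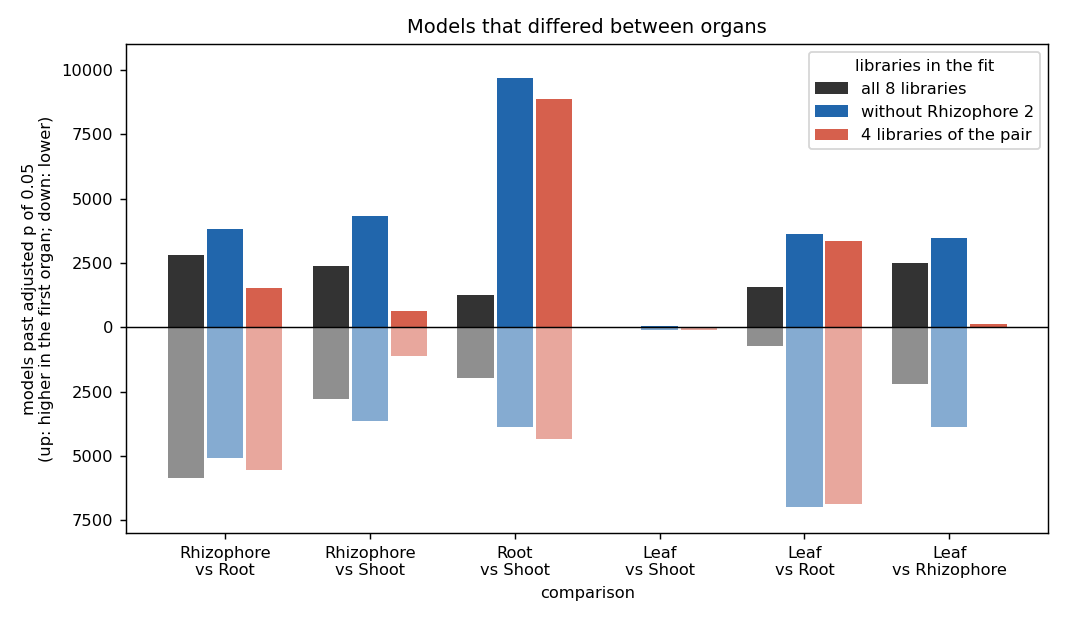
Number of models past an adjusted p of 0.05 in edgeR's test (vertical axis) for the 6 pairs of organs (horizontal axis), with models higher in the first organ drawn upwards and lower ones downwards in a paler shade. Bars compare the fit on all 8 libraries, the fit without Rhizophore 2 and the fit on the 4 libraries of the pair; root against shoot went from 3227 models to 13526 and 13205.

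Leaf and shoot differed in 3 models, all lower in leaf. The model 404435.v1 was at 4137 ± 358 CPM in shoot (SD, n = 2) and 7.55 ± 4.58 CPM in leaf, a log2 fold change of -9.04 (SE 0.64, edgeR adjusted p = 0.00144). The model Smoe_00038536 was at 346 ± 113 CPM in shoot and 3.14 ± 1.39 CPM in leaf, a change of -6.69 (SE 0.52, adjusted p = 0.00189). The third, 3016.v1, named after its values were seen because the list is this short, was at 358 ± 127 CPM in shoot and 22.3 ± 2.24 CPM in leaf, a change of -4.00 (SE 0.43, edgeR adjusted p = 0.0264). All 3 were also higher in shoot than in root and in rhizophore. At an unadjusted p under 0.05 in edgeR's test the count was 727 of the 23662 tested. That share is below the 0.05 that unchanged models would give, so it is by itself no sign of further differences.

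The leaf and shoot count was 126 in a fit on these 4 libraries alone (14 higher and 112 lower in leaf), 62 with DESeq2 and 2 with limma-voom, 128 without the library labelled rhizophore replicate 2 and 149 without rhizophore replicate 1, and 1 with replicate 2 counted as root. It was 0 without root replicate 1 or 2 and without leaf replicate 1 or 2, in edgeR's test, with all 3 calls ended (adjusted p of 0.119 to 1; 3.6e-144 to 0.254 for 404435.v1 and 4.0e-95 to 0.254 for Smoe_00038536 over all alternatives), and 2 without shoot replicate 1, where 3016.v1 was no longer called (edgeR adjusted p = 0.11, with 2.7e-48 to 1 over all alternatives).

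Against root, 1576 models were higher in leaf and 734 lower, 2310 in all, and against rhizophore 2514 were higher in leaf and 2210 lower, 4724 in all. The leaf and root direction turned in other fits. It was 3635 higher and 6968 lower without the library labelled rhizophore replicate 2, 2364 and 5052 with limma-voom, and 3340 and 6865 with the 4 libraries alone, and DESeq2's test gave 5244 models, 2600 higher and 2644 lower. That count was 10740 without rhizophore replicate 1 (3551 higher, 7189 lower), 1432 with replicate 2 counted as root, 83 and 524 without root replicate 1 or 2, 548 and 686 without leaf replicate 1 or 2, and 1448 and 1454 without shoot replicate 1 or 2. The balance between leaf and rhizophore turned too, to 3484 higher and 3877 lower without the library labelled rhizophore replicate 2, 4492 and 5310 without replicate 1, and 3407 and 3790 with DESeq2, which made totals of 7361, 9802 and 7197. It was 128 and 9 with the 4 libraries alone, 137 in all, and the total was 1934 and 2340 without leaf replicate 1 or 2 and 0 with rhizophore replicate 2 counted as root.

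The series compared its 3 growth centres, and models were grouped by which of shoot, root and rhizophore exceeded which. The rhizophore exceeded both others in 1158 models, the shoot in 948 and the root in 444. limma-voom turned this order, to 1018 for rhizophore, 1402 for shoot and 4141 for root, whereas DESeq2 gave 1667, 1373 and 987. The leading rhizophore model, 91546.v1, was at 58.5 ± 42.9 CPM in rhizophore (SD, n = 2), 0.880 ± 0.516 CPM in shoot and 0.210 ± 0.0823 CPM in root. The leading root model, 427960.v1, was at 72.4 ± 18.1 CPM in root, 0.259 ± 0.367 CPM in shoot and 0 in both rhizophore libraries, and the leading shoot model was Smoe_00044417. Independent lists of the sizes in edgeR's fit would share 281, 235 and 307 models for rhizophore, shoot and root. Both tests of a class share the libraries of its organ, so part of any excess may come from them. Without the library labelled rhizophore replicate 2 the counts were 2094 for rhizophore, 1713 for shoot and 2860 for root. With it counted as root they were 4, 6 and 62, of which 0, 6 and 0 were in the classes above.

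Root and shoot together exceeded the rhizophore in 1631 models, rhizophore and shoot exceeded the root in 930, and rhizophore and root exceeded the shoot in 517. The respective counts for independent lists were 693, 235 and 124, and 20 simulations of unchanged groups gave at most 3 models. Those simulations called at most 8 models per comparison, so they give chance with no effect and equal spread in all organs. They are no measure for lists as long as these. Part of each excess may come from the libraries that both tests of a class share, since 2 libraries could not be split. The leading models were 137813.v1 for root and shoot, Smoe_00049080 for rhizophore and shoot, and 105912.v1 for rhizophore and root. The model Smoe_00049080 was at 5260 ± 107 CPM in shoot and 21.0 ± 13.4 CPM in root (SD, n = 2), but at 5936 CPM in rhizophore replicate 1 and 103 CPM in the library labelled rhizophore replicate 2. The model 105912.v1 was at 72.4 ± 55.8 CPM in root, 52.1 ± 30.03 CPM in rhizophore and 2.48 ± 0.0122 CPM in shoot. Without the library labelled rhizophore replicate 2 the class of rhizophore and root held 2222 models, that of rhizophore and shoot 2105 and that of root and shoot 2390. With it counted as root they held 0, 219 and 2, of which 0, 31 and 0 were in the classes above.

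The same classes moved with other libraries. Leaving out root replicate 1 gave 402 models for rhizophore over both others, 31 for root and 95 for shoot, with 14 for rhizophore and root, 62 for rhizophore and shoot and 781 for root and shoot. In the same order, the counts were 393, 63, 221, 132, 189 and 891 without root replicate 2, 280, 45, 305, 35, 327 and 856 without shoot replicate 1, and 304, 45, 293, 55, 328 and 861 without shoot replicate 2. Without rhizophore replicate 1 they were 2820, 2329, 2312, 3559, 1407 and 3149. Without leaf replicate 1 or 2 the shoot class fell to 625 each time and that of rhizophore and shoot to 596 and 592. Among the leading models, 91546.v1 lost a call without either shoot library or root replicate 1 (edgeR adjusted p of 0.0594 to 0.0956) and 427960.v1 without either root library or shoot replicate 2 (0.0521 to 0.0922). The model 105912.v1 lost one without root replicate 1 (edgeR adjusted p of 0.0505), and Smoe_00049080 did so without any 1 of the shoot, root or leaf libraries (0.0552 to 0.211). Over all alternatives the adjusted p of these 4 models ranged from 2.5e-107 to 0.541.

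**Figure D4:**
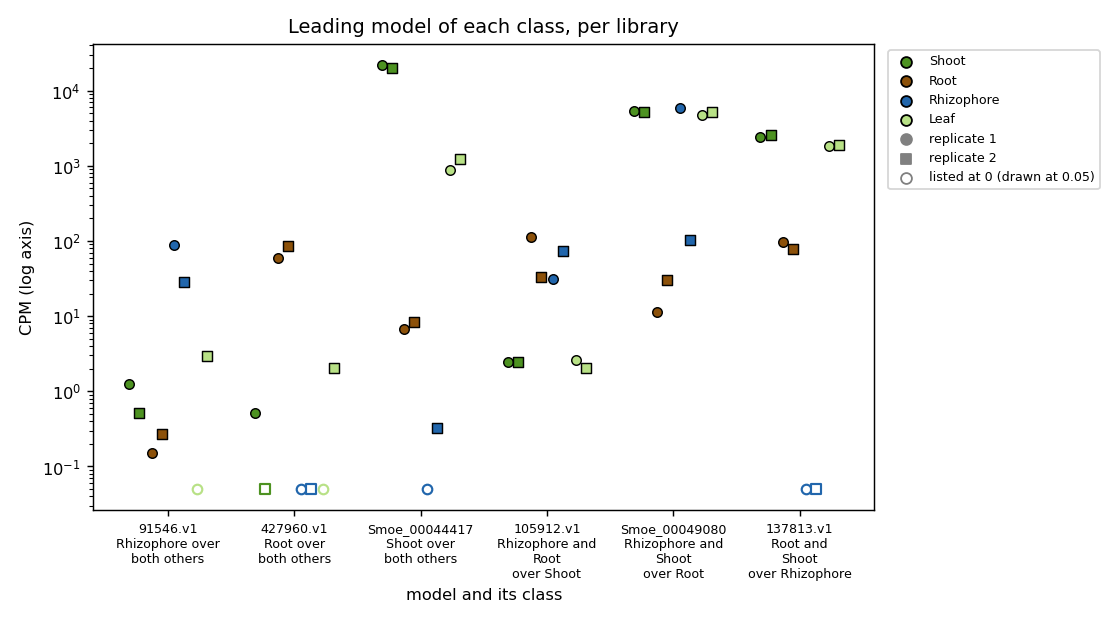
Level in CPM (log axis) of the leading model of each class of growth centres (horizontal axis) in all 8 libraries; circles are replicate 1, squares replicate 2, colours the organs, and open symbols drawn at 0.05 are libraries listed at 0. Smoe_00049080 was at 5936 CPM in Rhizophore 1 and 103 CPM in Rhizophore 2, whereas 137813.v1 was listed at 0 in both.

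With the leaf included, 1063 models were highest in rhizophore, 237 in root, 3 in shoot and 0 in leaf by edgeR's test. The 3 shoot models of that test were those that differed between leaf and shoot. The order turned with limma-voom, at 716 in rhizophore and 3257 in root, whereas DESeq2 gave 1552 in rhizophore, 674 in root and 40 in shoot. For leaf, 6 models passed all tests at an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0, and edgeR called 12 and 11 without rhizophore replicate 1 or 2. The rhizophore count was 1967 without the library labelled rhizophore replicate 2 and 2727 without replicate 1. With replicate 2 counted as root, 0 models were highest in rhizophore, 61 in root, none of them among the 237, and 1 in shoot. The rhizophore count was 279 and 302 without shoot replicate 1 or 2, 380 and 359 without root replicate 1 or 2, and 282 and 409 without leaf replicate 1 or 2. For root the count was 2517 and 1946 without rhizophore replicate 2 or 1, and 18, 55, 42, 43, 24 and 48 without root, shoot and leaf replicates 1 and 2 in that order. For shoot it was 66 and 63 without rhizophore replicate 2 or 1, and 0 without either root or either leaf library.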

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

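The tests of the authors' Root average, and the fits that leave root or rhizophore libraries out of the comparison of leaf and shoot, were chosen as tests after their values had been seen, as was the rule that the whole interval for background reads must lie above 90%, and the remaining tests in this part were fixed before. The Wilson intervals in this part treat models as independent draws, so they are too narrow where models vary together and do not cover the spread between libraries.

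The column labelled rhizophore replicate 2 carried 49.6% of the authors' deposited Root average, a signal in a table that the comparisons between organs do not use. A fit that merely confuses similar profiles was argued against, because leaving the column out raised the median relative residual of that average from 1.27% to 29.3%, a ratio of 23.01. A column holding only root tissue like that of the root libraries was argued against as well. The test took 653 models with a root mean of at least 10 CPM and at least 8-fold higher in both root libraries than in rhizophore replicate 1. Of these, the column lay nearer the root mean for 30.78% (95% Wilson interval 27.4 to 34.4%, and 25.8% of 1091 without the 10 CPM limit). They were chosen for high levels in both root libraries, so another library tends to lie farther from root. The column was 1.82 from rhizophore replicate 1 but 2.52 and 2.84 from the root libraries, which were 0.97 apart. Those distances also take in the low signal that the root libraries listed for nearly all models. The model 439279.v1 was at 4601 CPM in the column against 1.85 and 2.79 CPM in root. It was chosen with the column counted as rhizophore, so its level there is no evidence. A part of root tissue was not settled. Among 574 models of at least 10 CPM in rhizophore replicate 1 and at least 8-fold higher there than in root, the column lay nearer the root mean for 54.88% (50.8 to 58.9%, and 55.2% of 580 without the limit). These models were chosen for high levels in rhizophore replicate 1, so any other library tends to lie nearer root and the share cannot decide. Single models went both ways. Of those below, 427960.v1 and 105912.v1 were chosen with the column counted as rhizophore, so their levels in it cannot decide. The model 236852.v1 took 4.26% and 1.70% of root counts but 0.00488% of the column's, and 427960.v1 was at 59.6 and 85.2 CPM in root and 0 in the column. In contrast, 105912.v1 was at 112 and 33.0 CPM in root and 73.3 CPM in the column. An error in the authors' averaging could account for the weight but not for the column's place among the libraries, and a rhizophore nearer to forming roots for its place but not for the weight, and neither was tested.

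The root libraries listed 24582 and 24858 of 25004 models above 0, and the highest other library listed 19749. Greater depth was argued against, since both root libraries still listed at least 23804 models when thinned to 10063538 counts with values under 5 set to 0. A few abundant models taking the counts of the other libraries were also argued against: thinned to an equal total outside 152 abundant models, both root libraries listed at least 18038 models and no other library more than 15168. Reads spread over all models, such as from genomic DNA, stay open. Of the 3547 models at 0 in the other 6 libraries, 90.75% were above 0 in both root libraries (95% Wilson interval 89.8 to 91.7%). That share met the 90% set beforehand for this explanation, while its interval straddles 90%. The root libraries listed only 422 and 146 models at 0, so the share had to be high whatever the cause and cannot decide. The median level of the 3547 models was 0.760 CPM in root replicate 1 and 2.08 CPM in replicate 2. A broader set of models in use in root tissue, untested here, may give the same picture.

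Leaf and shoot differed in 3 models in the fit on all 8 libraries. A spread shared with the root and rhizophore libraries is a candidate explanation, since a fit on the 4 leaf and shoot libraries called 126 models, above the 30 set for it. Within it, the root libraries alone were argued against, because the fit without both of them called 0 models, whereas the fits without rhizophore replicate 2 or 1 called 128 and 149, as a spread set by the rhizophore libraries would give. The shoot samples bore microphylls per the labels, so shared leaf tissue stays open as a biological explanation and was not tested.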

How the results depend on the processing

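The fits that count the library labelled rhizophore replicate 2 as root, or leave out both root libraries, were chosen after the data were seen, and the others were planned. No named model reversed its direction: of 521 values for 27 comparisons of named models, 408 kept their side of the threshold, 108 no longer passed and 5 came to pass. Most named models were chosen for large folds, with both libraries of the higher organ above both of the lower. A reversal in refits of the same counts was therefore hardly possible, and its absence is no test of them. DESeq2's size factors and a log2 fold change of at least 1 moved no count by over 1.5 times, the margin used for counts below, although the size factors turned the balance between rhizophore and shoot to 2708 higher and 2678 lower. The cause of the changes was not tested except where stated. Depth limits models near the floor of 5 counts, most of all in leaf replicate 1 with 2826533 counts in total. Set tests of gene lists were not run because no list had a member, and alternatives for normalized values did not apply to counts.

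DESeq2's test gave 7837 models for rhizophore and shoot, 6510 for root and shoot, 62 for leaf and shoot, 5244 for leaf and root, and 7197 for leaf and rhizophore. It gave 674 models highest in root, 40 in shoot and 2 in leaf, with 987 for root over both other growth centres and 1874 for rhizophore and root over shoot. With limma-voom the counts were 9462 for root and shoot, 7416 for leaf and root, 3257 highest in root, 4141 for root over both other growth centres, and 858 for rhizophore and root over shoot. Without a filter there were 5648 models for rhizophore and root, 5 for leaf and shoot, and 5 highest in shoot. A filter of 10 CPM in 2 libraries, which tests fewer models, gave 4853 for rhizophore and root and 424 highest in root, and distances of 1.95 for rhizophore and root, 1.87 for root and shoot, and 1.95 for leaf and root. The rhizophore was then nearer to root than to shoot, whose distance was 2.15, the reverse of the order without this filter.

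The 4 libraries of a pair alone gave 1736 models for rhizophore and shoot, 13205 for root and shoot, 126 for leaf and shoot, 10205 for leaf and root, and 137 for leaf and rhizophore. Without leaf, 577 models were higher in shoot than in both other growth centres and 602 were shared by rhizophore and shoot. An adjusted p under 0.01, a stricter threshold by construction, left 2048 (1047 higher and 1001 lower in rhizophore), 2368 and 963 models for rhizophore and root, rhizophore and shoot, and root and shoot, and 757 and 2160 for leaf and root and leaf and rhizophore. It left 317 highest in rhizophore and 35 in root, 348, 51 and 344 for rhizophore, root and shoot over both others, and 55, 281 and 693 for the classes of rhizophore and root, rhizophore and shoot, and root and shoot.

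With the replicate number as a block, 3746 models differed between rhizophore and root (1882 higher and 1864 lower in rhizophore), 129 were highest in root, 168 were higher in root than in both other growth centres, and 298 were shared by rhizophore and root, while the other 12 counts stayed within that margin. The numbers were not taken to pair the libraries, since deviations of same-numbered libraries correlated by only -0.01 to 0.07. All 8 libraries correlated best with one of their own number, a hint from the data and not from the design. The libraries of an organ deviate from their mean by equal and opposite amounts, so these are not 8 separate outcomes.

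With the library labelled rhizophore replicate 2 counted as root, which leaves the rhizophore with 1 library, the counts were 384 for rhizophore and root (306 higher and 78 lower in rhizophore), 12 for rhizophore and shoot, 1757 for root and shoot, 1 for leaf and shoot, 1432 for leaf and root, and 0 for leaf and rhizophore. The models highest in rhizophore, root and shoot were then 0, 61 and 1, those over both other growth centres 4, 62 and 6, and those shared by rhizophore and root, rhizophore and shoot, and root and shoot 0, 219 and 2. Without both root libraries, the balance between rhizophore and shoot turned to 2293 higher and 2231 lower, and 0 models differed between leaf and shoot in edgeR's test.

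Leaving out each library in turn gave 1667 to 9471 models for rhizophore and root, 1842 to 10366 for rhizophore and shoot, 183 to 13584 for root and shoot, 0 to 149 for leaf and shoot, 83 to 10740 for leaf and root, and 1934 to 9802 for leaf and rhizophore. Models highest in rhizophore ranged from 279 to 2727, in root from 18 to 2517, in shoot from 0 to 66 and in leaf from 0 to 12. Models over both other growth centres ranged from 280 to 2820 for rhizophore, 31 to 2860 for root and 95 to 2312 for shoot. The shared classes ranged from 14 to 3559 for rhizophore and root, 62 to 2105 for rhizophore and shoot, and 781 to 3149 for root and shoot. The lowest counts mostly came without root replicate 1, and the highest without a rhizophore library. Distances ranged from 2.27 to 2.70 for rhizophore and root, 1.89 to 2.48 for rhizophore and shoot, 2.31 to 2.80 for root and shoot, 0.88 to 1.56 for leaf and shoot, 2.31 to 3.07 for leaf and root, and 1.92 to 2.50 for leaf and rhizophore.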

Other observations

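The test of the rhizophore's position was fixed before its values were seen, but the comparison with leaf that decides how it is read was added afterwards.

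The next most abundant shoot models after 236852.v1 were 139170.v1 and 137689.v1. The model 139170.v1 took 6.60% and 6.68% of shoot counts and 6.03% and 6.26% of leaf counts, 1.10% and 0.467% of root counts, and 0.0288% and 0.00483% of rhizophore counts. The model 137689.v1 took 5.36% and 5.47% in shoot, 5.61% and 5.62% in leaf, 0.110% and 0.0854% in root, 0.00295% in rhizophore replicate 1, and was listed at 0 in the library labelled rhizophore replicate 2.

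The direction of change in the authors' deposited table was that of the fit for all 5169 models that differed between rhizophore and shoot, for 95.4% of the 3227 between root and shoot, and for 92.4% of the 8662 between rhizophore and root. Their averages were made from the same counts, so this is no independent support, and their Root average holds the library labelled rhizophore replicate 2 at 49.6%, so that their groups are not those of the fit.

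A rhizophore profile intermediate between shoot and root was a hypothesis, to be read from the 3227 models that differed between these organs. Rhizophore replicate 1 lay between the shoot and root means for 58.4% of them and replicate 2 for 54.38%, both above the 50% set for the hypothesis. The leaf libraries also lay between for 73.6% and 62.1%, so the share does not single out the rhizophore and the hypothesis stays open. The median position, with 0 at the shoot and 1 at the root mean, was 0.44 and 0.65 for the rhizophore libraries and 0.06 and 0.02 for the leaf libraries.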
